A study of Mus musculus with 6 samples.

How the data were processed

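Uterine RNA from day 4 of mouse pregnancy was sequenced in 6 libraries, 3 control and 3 Zip10 cKO, and grouped by the sample titles. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, fragmented, primed with random primers and made into adaptor-ligated libraries. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10a, RSEM 1.3.3, R 4.2.1 and edgeR 3.38.4 and the genome build GRCm39 (mm39), with no parameters. The gene annotation release and the strand setting are not given in the sources used here.

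The authors deposited one RSEM gene table per library, with expected counts, in which reads shared by several genes are split between them, and with TPM, both per the file headers. The deposited TPM values divide each count by the effective gene length and scale each library to a fixed sum, so they keep no depth. Genes that share sequence with near-identical copies, such as immunoglobulin segments and the Klra family, have counts that depend on how RSEM split the reads. Of 56748 gene IDs, 52073 (91.8%) matched a symbol in the GENCODE M21 names. That annotation belongs to another build, so no coordinates are reported and it was used only for names and for which genes neighbour each other. Of 337 genes in the fixed lists, 2 did not match a symbol and 303 were tested.

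Expected counts were rounded to whole numbers. Genes were kept by filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), libraries were scaled by TMM, and the groups were compared by edgeR 4.0.16's quasi-likelihood test with robust estimation, in R 4.3.3, with Benjamini-Hochberg adjustment over the 16737 genes kept and a threshold of 0.05. All tests were two-sided unless named otherwise. The SE of a log2 fold change was taken from the F statistic. Values are given as CPM after TMM scaling, with SD over 3 libraries. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 3 and a preset correlation of 0.01, adjusted over the 23 lists with at least 3 measured members. The main design, the lists and the alternatives below, except where stated, were fixed before the data were examined.

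The genes named were fixed by a rule: Slc39a10; the 12 largest rises and 12 largest falls among genes past the threshold, with a mean of at least 1 CPM in the higher group and groups that do not overlap, leaving out predicted genes; up to 4 members of each list with the smallest p; and Pgr, Esr1, Ihh, Areg, Hand2, Il13ra2, Lif, Ltf, Muc1, Mki67, Mt1 and Mt2. No gene met the rule on rises and falls. Genes named from DESeq2 calls and in the closing section were chosen after their values were seen.

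The alternatives were DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, glmTreat at a minimum fold of 1.5, other normalizations and filters on low counts, limma-trend on deposited TPM with pseudocounts of 1 and 0.1, leaving out the 20 most abundant and all mitochondrial genes, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. Removing a trend of each library on gene length (loess, span 0.5), DESeq2 on the genes kept for edgeR, and the estimated correlation with a library left out or that trend removed were added after the data were seen.

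The scripts were tested on simulated counts for the 16737 genes of the Zip10 cKO against control comparison, with 200 changed genes, 50 of each fold. Each gene was drawn independently, and the changed genes were taken from those with a mean count of at least 50. The quasi-likelihood test recovered 12% of the genes changed 1.5-fold, 78% of those changed 2-fold and 100% of those changed 4-fold and 8-fold, with 11 false calls. DESeq2 recovered 32%, 86%, 100% and 100% with 49 false calls. Library pairs differed by more than sampling noise, with a chi-square per degree of freedom of at least 14.3, so no library was taken for a second copy of another. Total counts ranged from 19643069 to 22809574. Figures were drawn with matplotlib 3.10.9.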

Results

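RNA was sequenced from the uterus of mice on day 4 of pregnancy, at 1600 h, shortly before implantation begins in this species. The series compares controls with mice that lack the zinc transporter Zip10, encoded by Slc39a10, in the uterus (conditional knockout, cKO). Its title places the question in progesterone responsiveness, and the tissue is called endometrium in the series design and uterus in the sample labels. Each group held 3 libraries, and the labels do not say that each came from a separate animal, so the p-values measure only the spread between these samples. The summed gene counts were 22809574, 20176537 and 20986355 in controls 1, 2 and 3, and 21332846, 22328338 and 19643069 in cKO libraries 1, 2 and 3. Of 56748 genes in the tables, 16737 had enough counts to be tested.

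Slc39a10 (ENSMUSG00000025986), a plasma membrane zinc importer and the targeted gene, was not lower in the libraries labelled Zip10 cKO. Its level was 54.6, 70.4 and 66.2 CPM (counts scaled to a common library size) in controls 1, 2 and 3, and 39.5, 72.5 and 79.8 CPM in cKO libraries 1, 2 and 3. The group means were 63.7 ± 8.17 and 63.9 ± 21.4 CPM (SD, n = 3 each). The fold of cKO over control was 1.00, with a 95% interval from 0.678 to 1.49, and an exact two-sided permutation test of the CPM gave p = 1, where 3 against 3 cannot go below 0.1. Each library held 832 to 1606 counts of the gene, so depth was not the limit. The labels do not name the deleted exons and a gene total also counts reads from the exons that remain, so this total does not check the genotype labels. Every direction below is therefore that of the libraries labelled Zip10 cKO.

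**Figure D1:**
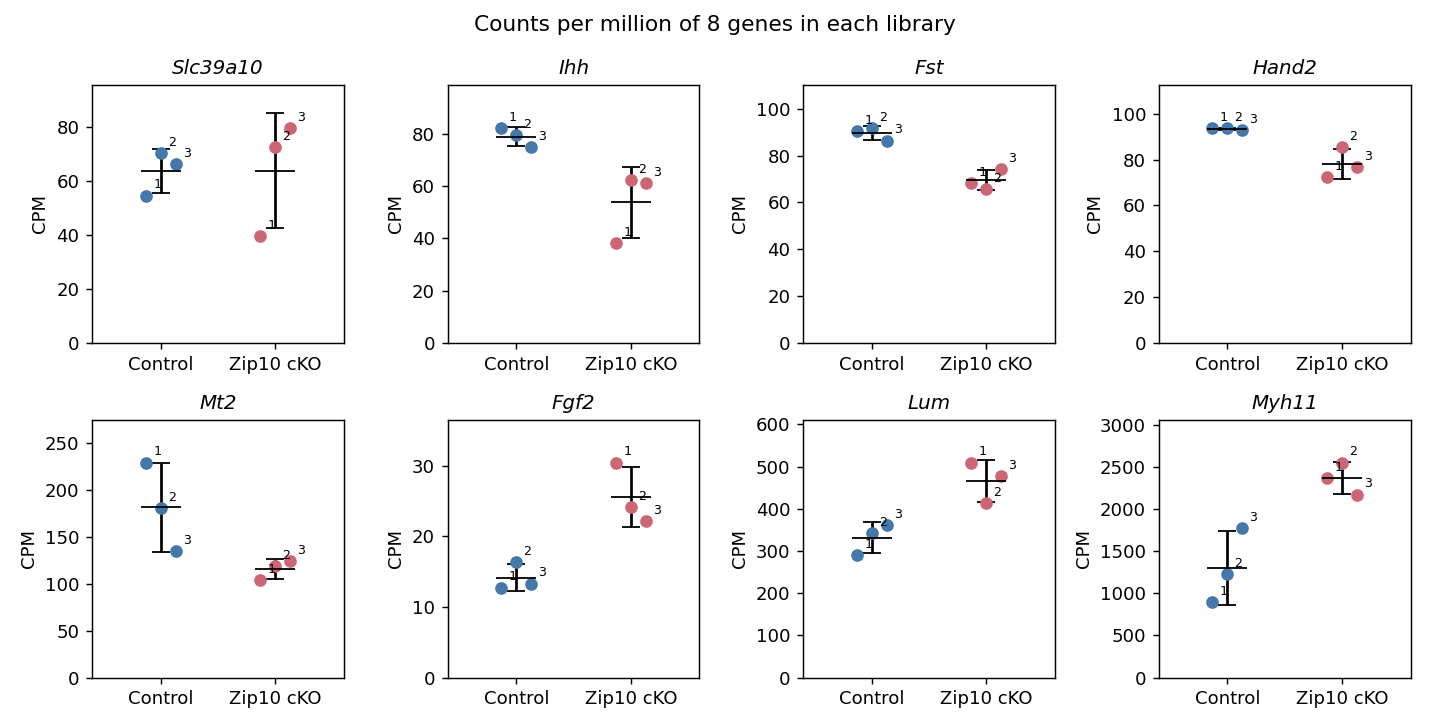
CPM (vertical axes, linear, from 0) of 8 genes in the 3 control and 3 Zip10 cKO libraries. Points are libraries with their replicate number, and the bar and whiskers are the mean and SD of each group. Slc39a10 overlapped between groups, and all 3 cKO libraries lay below all 3 controls for Ihh, Fst, Hand2 and Mt2 and above them for Fgf2, Lum and Myh11. The genes shown are a selection from those named by the rule, and others, such as Acod1, Mt1, Areg and Pgr, overlapped between groups. Over all genes tested, the groups did not overlap for 12.7%, where chance gives 10%.

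The first comparison asked which genes differ between the groups. No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, with or without a minimum absolute log2 fold change of 1, and the smallest adjusted p in that test was 0.626. At an unadjusted p under 0.05 there were 1081 genes, 749 higher and 332 lower in the cKO libraries, where chance alone gives 837. The 3 cKO libraries lay entirely on one side of the 3 controls for 2127 genes, 12.7% of those tested, where chance gives 10%. Among genes with small unadjusted p-values, singled out after their values were seen, were Itih5, an inter-alpha-trypsin inhibitor heavy chain of the extracellular matrix, at 137 ± 23.8 CPM in controls and 262 ± 50.5 CPM in cKO libraries (SD, n = 3 each), and Clec1b, a C-type lectin receptor of platelets, at 3.89 ± 0.641 and 1.05 ± 0.0479 CPM.

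Other tools counted differently. limma-voom called 0 genes, with 1074 at an unadjusted p under 0.05. edgeR's likelihood ratio test called 30 genes, 25 higher and 5 lower, with 1100 at an unadjusted p under 0.05, and DESeq2 called 37, 29 higher and 8 lower, with 1201 of 28970 genes against 1449 expected by chance. Both called 28. In 10 simulated sets in which no gene changed, the quasi-likelihood test called a median of 0 genes and at most 4, the likelihood ratio test a median of 10.5 and at most 15, and DESeq2 a median of 14 and at most 19. The likelihood ratio test and DESeq2 were not run on other splits of the real libraries. In the simulated sets each gene was drawn independently, unlike in the real libraries, so their counts may understate the calls made without a change. These sets held the 16737 genes tested by edgeR, and DESeq2 fitted anew to those genes alone called 34, 28 higher and 6 lower, with 1136 at an unadjusted p under 0.05. Of the 37 calls of the fit to all genes, 3 lay outside those genes, and the 2 sets of calls were not matched gene by gene. With each library left out in turn, the quasi-likelihood test called 0 genes except without cKO library 1, where it called 2, and with no filter on low counts it called 15. The DESeq2 calls named here were chosen after their values were seen. Higher genes included, by log2 fold change, the potassium channel gene Kcnn3 at 0.84 (DESeq2 adjusted p = 0.00305), the calcium channel gene Cacna1c at 0.81 (DESeq2 adjusted p = 0.00397) and the intermediate filament gene Synm at 0.91 (DESeq2 adjusted p = 0.0118). Myh11, a member of the smooth muscle list below, was called too, at 0.85 (DESeq2 adjusted p = 0.0470). Whether the higher calls follow the share of muscle in the tissue was not tested. Immunoglobulin segments made up 9 of the 37 calls, 8 higher and 1 lower. The DESeq2 log2 fold changes were 2.27 for Igkv10-96 and -1.56 for Iglc1. These segments share reads with near-identical copies, so their values are uncertain. Lower genes included Cdh10, a cadherin, at -1.06 (DESeq2 adjusted p = 0.00777), and Cd14, a receptor for bacterial lipopolysaccharide, at -0.54 (DESeq2 adjusted p = 0.0288).

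The second comparison took 25 gene lists fixed before the data were examined, of which 23 had at least 3 measured members, and asked whether each list stood apart from all other genes. The camera test of limma with a preset correlation of 0.01 called 10 lists, 6 higher and 4 lower. The correlations estimated for these lists ran from 0.05 (progesterone-responsive) to 0.92 (red blood cell genes), all above the preset value. With the correlation estimated from the data, limma's camera called 0 lists, and limma's fry, which tests whether members move one way without comparing them with other genes, called 0 with a lowest adjusted p of 0.441. Over all genes no list member passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and adjusted over the list alone 14 members did: 7 stromal, 3 smooth muscle, and 1 each among the macrophage, neutrophil, oestrogen-responsive and LIF pathway lists.

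The progesterone-responsive list, which bears on the question in the series title, was called as lower, with a median log2 fold change of -0.16 (limma camera adjusted p = 0.0355, and adjusted p = 0.636 with an estimated correlation). Of its 25 measured members, 16 were lower and 9 higher. The mean of its members overlapped between groups, at 0.06, -0.07 and 0.17 in controls 1 to 3 and -0.22, -0.10 and 0.17 in cKO libraries 1 to 3. These means are log2 CPM differences from the mean of the 6 libraries. The call was lost with the replicate number as a block (limma camera adjusted p = 0.110) and when any 1 of the 6 libraries was left out, with medians from -0.31 to -0.15; the median was -0.25 without control 3, -0.25 without cKO library 2 and -0.31 without cKO library 3. None of its members passed the test over the list alone. Ihh, the hedgehog ligand that the progesterone receptor induces in epithelium, was at 78.8 ± 3.62 CPM in controls and 53.8 ± 13.6 CPM in cKO libraries (SD, n = 3 each), a log2 fold change of -0.55 ± 0.18 (SE). Fst, the activin antagonist follistatin, was at -0.37 ± 0.09, Hand2, a stromal transcription factor that restrains epithelial growth, at -0.26 ± 0.09, and Acod1, an enzyme of itaconate synthesis, at -1.02 ± 0.33, all as log2 fold change with SE. All 3 cKO libraries lay below all 3 controls for 5 members, among them Ihh, Fst and Hand2 but not Acod1, and above all 3 for 2 members. Areg, another progesterone target, gave -0.59 ± 0.43, and Il13ra2 gave 0.01 ± 0.24. Beside this list, the epithelial markers had a median log2 fold change of -0.25 and the stromal markers one of 0.48.

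The receptors themselves differed by less than the error. Pgr, the progesterone receptor, had a log2 fold change of -0.14 ± 0.18 and Esr1, the oestrogen receptor, one of 0.04 ± 0.13. In their list, which camera did not call (limma camera adjusted p = 0.886), 8 of 15 members were higher and 7 lower. Fkbp4, a chaperone of the progesterone receptor, stood at -0.42 ± 0.17. After the length trend of the libraries was removed, an alternative chosen after the data were seen, the list was called as lower, with a median of -0.08 (limma camera adjusted p = 0.00164; adjusted p = 0.390 with an estimated correlation). The oestrogen-responsive list was not called (limma camera adjusted p = 0.354), with 9 of 17 members higher, though the mean of its members was higher in each cKO library (0.07 to 0.19) than in each control (-0.15 to -0.08). Fgf2, a growth factor, was the member that passed adjusted over the list alone: 14.1 ± 1.94 CPM in controls and 25.6 ± 4.30 CPM in cKO libraries (SD, n = 3 each), a log2 fold change of 0.86 ± 0.16. Greb1 gave 0.70 ± 0.23, the secretory epithelial gene Ltf, lactoferrin, 1.15 ± 0.88 and the mucin gene Muc1 -0.21 ± 0.21.

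Zinc transporters and metallothioneins, 23 measured members, were not called (limma camera adjusted p = 0.813), 13 higher and 10 lower, and no member passed over the list alone. Mt2, a metal-binding protein induced by zinc, was at 182 ± 47.2 CPM in controls and 116 ± 10.8 CPM in cKO libraries (SD, n = 3 each), a log2 fold change of -0.65 ± 0.18, and Mt1 gave -0.32 ± 0.15. Slc30a4, a zinc exporter, gave 0.17 ± 0.08. Slc39a12 lay at 1.22 ± 0.52, from levels of 0.458 and 1.07 CPM.

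In the lists that follow the hedgehog and LIF pathways, no call was made (limma camera adjusted p = 0.813 for both). Gli2, a transcription factor of the hedgehog pathway, had a log2 fold change of 0.32 ± 0.10, the hedgehog co-receptors Gas1 and Boc 0.45 ± 0.15 and 0.57 ± 0.20, and Gli1 -0.22 ± 0.10. Itgav, an integrin subunit, passed adjusted over the LIF pathway list alone, at 0.46 ± 0.11. Lif, the cytokine that implantation needs, had a log2 fold change of 0.29 ± 0.44, and Msx1 -0.56 ± 0.25. Among cell cycle genes 15 of 29 were higher, with no call (limma camera adjusted p = 0.813); Mki67, a proliferation marker, stood at 0.37 ± 0.26. Without cKO library 1 the cell cycle list was called as lower, with a median of -0.31 (limma camera adjusted p = 4.1e-07; adjusted p = 0.703 with an estimated correlation).

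Of the other lists without a call, prostaglandin synthesis and signalling included Ptger4, a prostaglandin receptor, at -0.47 ± 0.18 and Ptgis, prostacyclin synthase, at 0.40 ± 0.17. The ion channel and aquaporin list included Aqp5 at 1.42 ± 0.60 and Aqp11 at -0.74 ± 0.32, both water channels. In the Wnt list, Wnt7b gave 1.09 ± 0.33 and Sfrp2, a secreted Wnt antagonist, -0.34 ± 0.15. Uterine gland markers included Sox9 at 0.91 ± 0.34 and Ttr at -0.76 ± 0.31. Interferon response genes had a median log2 fold change of -0.07, and Irf7 gave -0.28 ± 0.20. The interferon list was called as lower without control library 2, with a median of -0.16, or without cKO library 1, with one of -0.15 (limma camera adjusted p = 0.0407 and 0.0218; adjusted p = 0.677 and 0.731 with an estimated correlation). Without control library 2 the immediate early and heat shock list was called as higher, with a median of 0.26 (limma camera adjusted p = 0.0262; adjusted p = 0.677 with an estimated correlation), and Atf3 stood at 0.67 ± 0.23 over all 6 libraries. The ovary and oviduct list was not called, with Star at 0.38 ± 0.15. The median, mean and test of 7 lists differed in sign: steroid receptors, LIF pathway, cell cycle, prostaglandin, ion channel, Wnt and gland lists. Blastocyst genes had 2 measured members and were not tested, with Eomes at 0.29 ± 0.21.

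The unfolded protein response list was called as lower, 11 of 12 members, with a median log2 fold change of -0.25 (limma camera adjusted p = 0.0355; adjusted p = 0.636 with an estimated correlation). Its transcription factor Xbp1 gave -0.23 ± 0.11, and the chaperone partner Sdf2l1 -0.62 ± 0.32. The call was lost without control library 2 or 3, without cKO library 1 or 3, and after the length trend of the libraries was removed (limma camera adjusted p = 0.237). The median was -0.40 without control 1 and -0.42 without cKO library 2, where the call held. Removing the trend did not shrink the median, which was -0.25 before and after, nor widen the spread of members beyond an SD of 0.33 against 0.32, so why that call ended is not known. Beside this list, the epithelial markers had a median of -0.25, the endothelial markers one of -0.16 and the stromal markers one of 0.48. Whether the list moved with the mix of cells was not tested.

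The third comparison asked which cell types and other sources of RNA moved with the group. Stromal cell markers were called as higher, 12 of 13 members with a median log2 fold change of 0.48, and smooth muscle markers too, 12 of 12 with a median of 0.54 (limma camera adjusted p = 2.06e-06 for both; adjusted p = 0.636 for both with an estimated correlation). Lum, a collagen-binding proteoglycan, was at 332 ± 36.5 CPM in controls and 466 ± 49.0 CPM in cKO libraries, and Myh11, the smooth muscle myosin heavy chain, at 1301 ± 442 and 2363 ± 189 CPM (SD, n = 3 each). Postn, periostin, had a log2 fold change of 0.88 ± 0.24 and Col3a1, a fibrillar collagen, 0.49 ± 0.14. Macrophage markers were called as higher, 10 of 10 with a median of 0.57 (limma camera adjusted p = 0.000361; adjusted p = 0.636 with an estimated correlation), with Mrc1, a mannose receptor, at 0.81 ± 0.20. These 3 lists were called without each library in turn. Without cKO library 1 the macrophage median was 0.22 (limma camera adjusted p = 0.0168), and without control 3 the smooth muscle median was 0.86. The macrophage mean of cKO library 2 (-0.19) lay below that of control 3 (-0.12).

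Lymphocyte markers (median 0.63, limma camera adjusted p = 0.0108), neutrophil markers (3 genes, median 0.93, adjusted p = 0.0146 from limma camera) and red blood cell genes (median 0.32, adjusted p = 0.0355 from limma camera) were also called as higher. Their adjusted p with an estimated correlation in limma camera was 0.636, 0.636 and 0.655. The lymphocyte list included Prf1, perforin of cytotoxic cells, at 0.71 ± 0.22, and the NK cell receptor gene Klrb1c at 1.35 ± 0.37. Klrb1c is among the NK gene complex genes of the closing section, and whether its rise follows the number of cells was not tested. The lymphocyte list had a median of -0.10 without cKO library 1 and 0.31 without control library 2 and lost its call in both. The neutrophil call was lost without control library 2 or 3 or cKO library 1 or 3, and that of red blood cells without control library 3 or cKO library 2 or 3. The red blood cell median was 0.12 without control 3 and 0.54 without control 1.

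Epithelial cell markers were called as lower, 11 of 13 with a median log2 fold change of -0.25, and endothelial cell markers, 10 of 12 with a median of -0.16 (limma camera adjusted p = 0.0355 for both; adjusted p = 0.729 and 0.636 with an estimated correlation). Epcam, an epithelial adhesion molecule, gave -0.33 ± 0.14, Cldn3, a tight junction protein, -0.57 ± 0.22 and Emcn, a sialomucin of endothelium, -0.36 ± 0.12. Krt7 went the other way at 0.44 ± 0.15. The epithelial call was lost without control library 1 or 2, without cKO library 1 or 3, and after removal of the length trend (limma camera adjusted p = 0.0864), where the median was -0.28 (SD of members 0.31, as before). The median was -0.12 without cKO library 1, and -0.47 without control 3 and -0.51 without cKO library 2, where the call held. The endothelial call was lost without control library 2 or 3 or cKO library 1 or 3, with medians of -0.09 without control 3 and -0.07 without cKO library 1, and held without control 1, with one of -0.25.

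**Figure D2:**
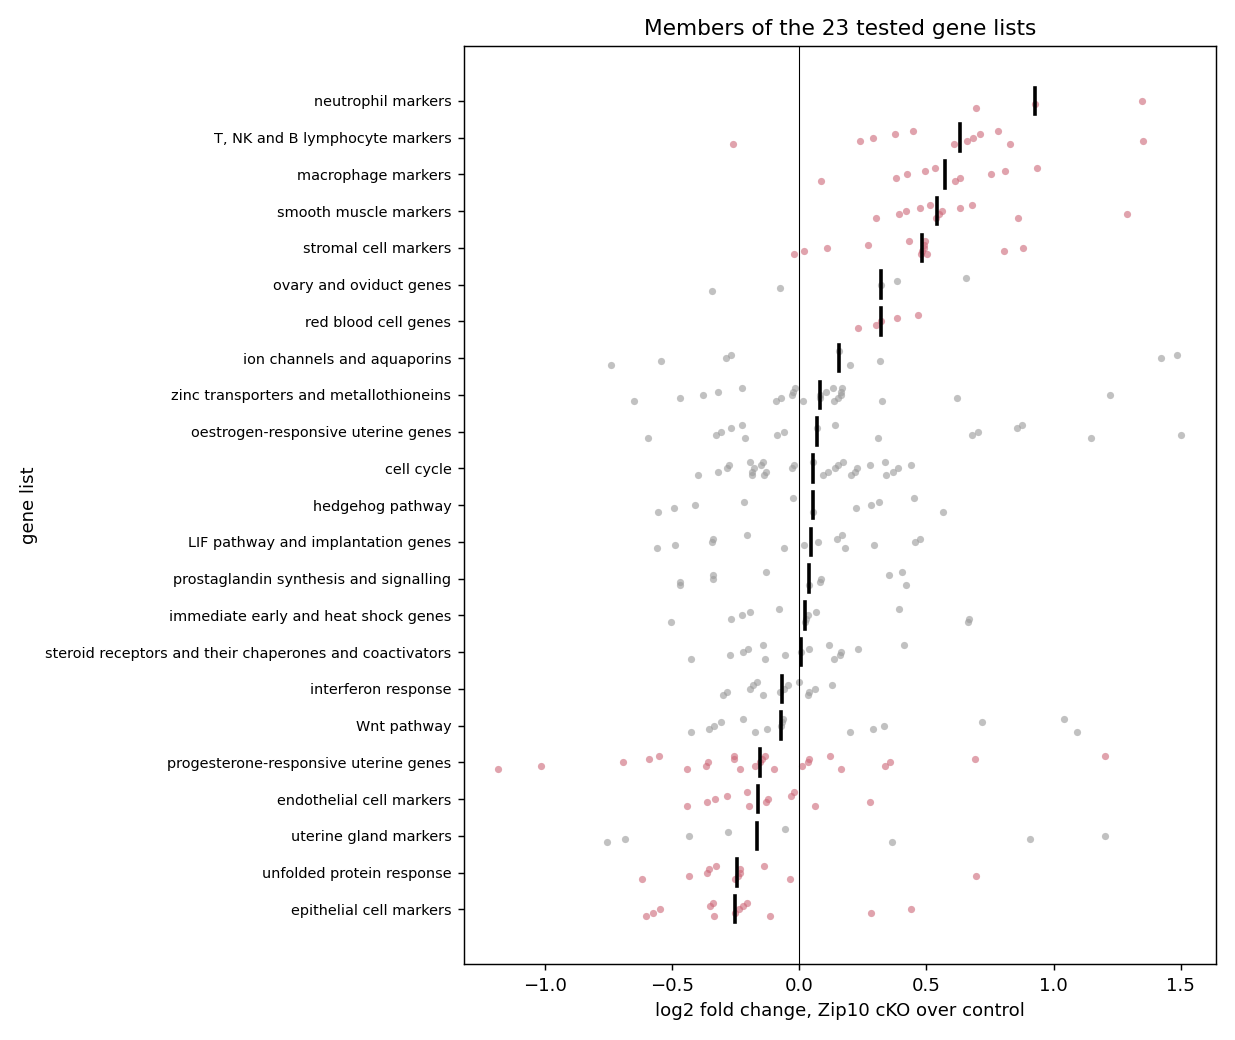
Log2 fold change of Zip10 cKO over control (horizontal axis) for the members of the 23 tested gene lists (vertical axis). Points are genes, black bars are list medians, and lists called by camera with a preset correlation are red and the others grey. The stromal median was 0.48 and the smooth muscle median 0.54, while the epithelial median was -0.25 and the progesterone-responsive median -0.16.

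**Figure D3:**
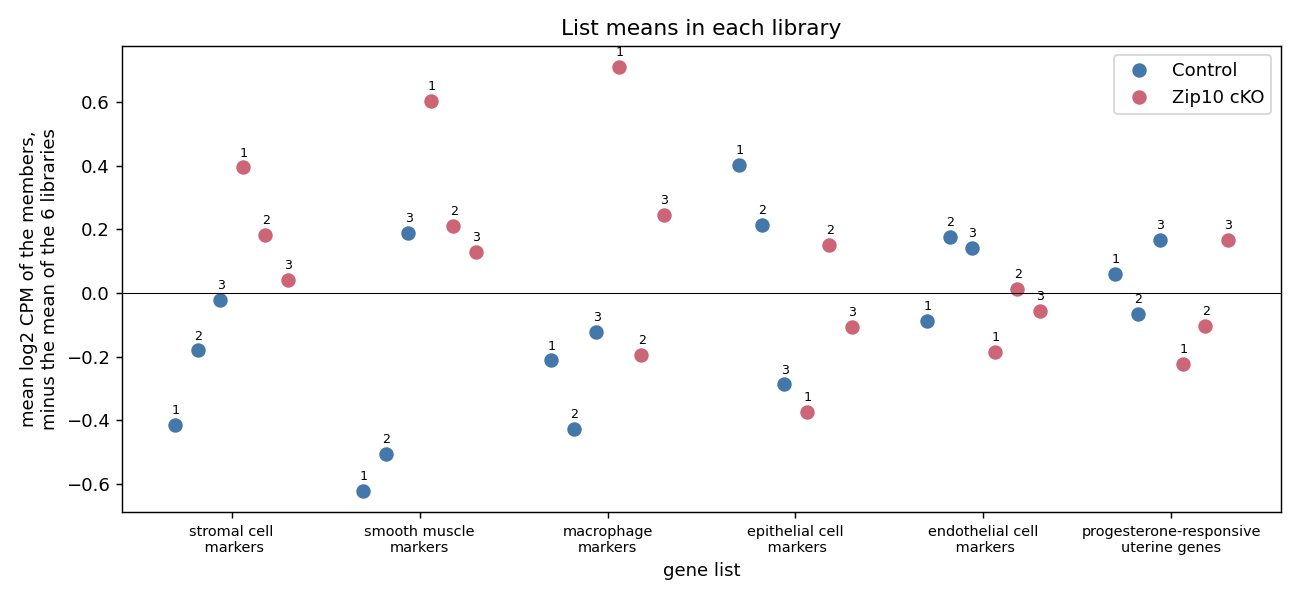
Mean log2 CPM of the members of 6 lists in each library, as the difference from the mean of the 6 libraries (vertical axis), with control libraries in blue, Zip10 cKO libraries in red and replicate numbers beside the points. All 3 cKO libraries lay above all 3 controls for the stromal markers, and the groups overlapped for the smooth muscle, macrophage, epithelial, endothelial and progesterone-responsive lists.

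The libraries also differed beyond the groups. cKO library 1 stood apart on the first dimension of a multidimensional scaling plot, at -1.58 against values between -0.02 and 0.77 for the others. Mitochondrial genes took 3.43% of its counts and 4.50% to 4.84% of those of the other 5 libraries. Across all genes, the median log2 fold change was -0.11 in the shortest quintile of gene length and 0.11 in the longest.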

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

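The length trend, DESeq2 on the genes kept for edgeR and the estimated correlation with a library left out or the trend removed were chosen after the data were seen. The count of genes called was 0 with edgeR's quasi-likelihood test under every normalization, and 0 too under glmTreat, limma-voom, both TPM settings, the fit without abundant and mitochondrial genes, the filter of 1 CPM in 3 libraries, the replicate block and the length trend. It was 37 by DESeq2 (20 with an absolute log2 fold change of at least 1), 34 by DESeq2 on the genes kept for edgeR (14), 30 by the likelihood ratio test (17) and 15 with no filter on low counts (8). Leaving out each library gave 0 to 2 genes (0 to 2 with the fold limit), 4 to 8 lists, 4 to 7 marker lists, a progesterone-responsive median from -0.31 to -0.15 (-0.18 without control 2, -0.25 without control 3 or cKO library 2), and a Slc39a10 log2 fold change from -0.19 to 0.26.

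The number of lists called was 10, of which 8 were marker lists, with RLE, library size only and the stricter filter as well. With an estimated correlation it was 0 and 0, also with each library left out and the length trend removed. With all 6 libraries the estimates were 0.66 for smooth muscle, 0.53 for stromal, 0.57 for macrophage and 0.51 for epithelial markers, against the preset 0.01. The progesterone-responsive list lost its call at an estimate of 0.05. With fry the number was 0 and 0. How much of the camera losses came from the size of the estimates was not tested, nor was the cause of the fry losses. The progesterone-responsive median was -0.16 under the replicate block, where its call was lost (limma camera adjusted p = 0.110), and -0.16 with an estimated correlation and with fry, where it was lost too. The labels state no pairing by replicate number. Same-numbered libraries had correlations of deviations of 0.09, 0.25 and 0.19, against -0.33 to 0.12 for the other pairs. In all, 5 of 6 libraries correlated best with their own number, while cKO library 1 correlated best with control 3, at 0.12. The deviations were taken from means of 3 libraries, so these values are not independent and do not decide whether the libraries were paired. The block left 9 lists and 0 genes called.

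Slc39a10 was not called under any of these settings, and its sign changed between them from a value with all 6 libraries of 0.00 ± 0.24 (SE). Among 2378 values of 114 named genes under the alternatives, 49 passed the threshold where the main test had none, all in DESeq2, the likelihood ratio test or the unfiltered test, and 0 reversed beyond their error. In the simulated data, with 3 libraries per group, changes of 1.5-fold were mostly missed even among the well-counted genes that were changed. Depth was not varied.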

Other observations

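All tests in this part except the number of lists called in other splits were chosen after the result was seen, and the marker lists for adipocytes, squamous epithelium, urothelium and NK cells were written after genes of these kinds had been noticed.

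Genes of other tissues appeared in 1 or 2 libraries. The 10 listed genes of stratified squamous epithelium summed to 45.9 CPM in cKO library 3 and to between 6.79 and 10.5 CPM in the other 5. The keratin genes Krt5 and Krt15 had 269 and 268 counts there, and 0 to 3 and 0 to 4 counts in the others. The 10 listed adipocyte genes summed to 68.9 CPM in control 3 and 51.5 CPM in cKO library 3, and to between 12.1 and 24.2 CPM in the other 4, and Adipoq, adiponectin, had 85 and 51 counts in those libraries and 0 to 3 in the others. The 5 listed urothelial genes summed to 22.1 CPM in control 1 and to between 5.14 and 11.5 CPM in the others, with Upk1b at 292 counts in control 1 and 88 to 234 in the others. Upk3a had 37 counts in control 1 and 0 or 1 in the other libraries, and Upk2 had 42 and 0 to 4.

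Other genes were present or nearly absent by library. Outside immunoglobulin and T cell receptor segments, 79 genes had at most 2 counts in at least 1 library and at least 30 in another. Of these, 20 were at most 2 counts in cKO library 1 alone, against 2 to 6 in each other library alone. Thsd7b had 1 count in cKO library 1 and 38 to 68 in the others. Zfp990 had 0 and 1 counts in control 1 and cKO library 1, and 127 to 185 in the other 4, and Masp2 had 1 and 1, and 25 to 42.

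With the preset correlation alone, and not with an estimated one or fry, stromal, smooth muscle and macrophage lists were called higher and epithelial, endothelial and progesterone-responsive lists lower in the cKO libraries; of these 6 lists only the stromal one had means that parted the groups. Longer genes were higher in the cKO libraries, with a median log2 fold change of 0.11 in the longest quintile of genes and -0.11 in the shortest, but the median of the stromal and smooth muscle members was 0.45 after this trend was removed (SD of members 0.28) and 0.49 before, which argues against length as the whole cause. A lower share of epithelium alone would raise the other cell types alike, but the endothelial median lay below the stromal one, with a difference of -0.65 against a combined SD of members of 0.34. It would also not lower progesterone-responsive genes of the stroma. The 6 listed ones had a median of -0.19, below that of the stromal markers. The difference was -0.68 against a combined SD of 0.36. Both SDs are spreads between genes and do not measure how far either gap would vary between libraries. Over the alternative settings, the endothelial median ran from -0.25 to -0.07 and the stromal marker median from 0.35 to 0.56. The 6 stromal progesterone-responsive genes went both ways, with Wnt4 at 0.36 and Bmp2 at 0.03. The 8 listed epithelial ones had a median of -0.50, against -0.25 for the epithelial markers. Both sets came from a list already called lower, so these medians do not tell a progesterone effect from a different mix of tissue. A different share of muscle wall in the tissue taken may account for the smooth muscle rise and cannot be told apart from genotype, since the control libraries alone ranged over 0.81 in the smooth muscle mean and the groups differed by 0.63; an effect of genotype stays open as well.

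Slc39a10 totals were not lower in the libraries labelled cKO. A loss of the whole message from most of the RNA is argued against by the lower bound of the 95% interval of the log2 fold change, -0.56, where such a loss needs -1 or less. Message from exons outside the deletion may remain, which gene totals cannot show. The transcript-weighted gene length changed by -0.69% between groups, and that excludes nothing. Swapped or wrong labels cannot be told apart from this either: 0 control libraries lay below 0.5 times the median control, but no library shows a fall that would mark a knockout.

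Some genes of the NK gene complex, a cluster of NK cell receptor genes, were nearly absent from some libraries. Klra8 had 1, 3, 2, 2, 73 and 51 counts and Klri2 0, 0, 0, 0, 65 and 62 in controls 1 to 3 and cKO libraries 1 to 3, while Klrd1 in the same complex had between 150 and 183. A different share of NK cells as the cause of this pattern is argued against: 11 NK cell genes outside the complex, 4 of them also in the fixed lymphocyte list, summed to at most 1.82 times the lowest library, and Klra8 to 76.4 times (95% counting interval 13.3 to 3059). The sum of those 11 genes was 186, 169 and 142 CPM in the cKO libraries and 130, 103 and 133 CPM in the controls. Not every gene of the 11 parted the groups as the sum did. Gzma did, with 149, 155 and 191 counts in controls 1 to 3 against 319, 234 and 270 in the cKO libraries. Ncr1 overlapped, with 186, 90 and 112 counts against 116, 86 and 111. The cKO library with the highest sum, library 1, had 2 counts of Klra8. Some genes of the complex parted the groups, in counts of controls 1 to 3 against cKO libraries 1 to 3. Klrb1b had 5, 4 and 6 against 22, 63 and 37, and Klrc2 10, 7 and 13 against 25, 37 and 41. Clec1b, named above, had 105, 69 and 77 against 21, 23 and 22. Klra17 and Klra2 did not part them. A candidate explanation is a strain variant that segregates between these libraries. For genes that part the groups it cannot be told apart from genotype, and the ratio for Klra8 does not cover them. The genes first noticed were Clec1b, Klrb1b, Klrc2, Klrb1c, BC064078, Klri2, Klra8, Klra17 and Klra2. Among the other 29 measured genes of the complex, 3 differed over 4-fold between libraries. Of the 16483 genes outside it with a mean count anywhere in the wide range of those 29, 5.89% did (one-sided Fisher's exact p = 0.243). Abundance was thus not matched closely. The test decides nothing, and reads shared between Klra copies stay open.

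The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 0 genes, as did 7 others, and the highest other gave 8; that 10 of 10 splits reach a count of 0 says nothing. It gave 1081 genes at an unadjusted p under 0.05, which 3 of the 10 splits reached, with a highest other of 1635. It called 10 lists, which 1 of the 10 splits reached, the real one, with a highest other of 8. The split with 8 genes and 1635 at an unadjusted p under 0.05 set controls 1 and 2 and cKO library 2 against the rest, as a structure of the samples other than the groups would, but the split was picked by its value and no test of such a structure was run.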
